A study of Glycine max with 22 samples.

How the data were processed

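Total RNA of 22 mature leaf samples of soybean was labelled with biotin by the one-cycle Affymetrix protocol and hybridised to Affymetrix Soybean GeneChips, per the labels' protocols. Plants grew in chambers with 16 h days, and leaf RNA was purified over a column after extraction, per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale for 61170 probe sets. In the deposited values each array has a 2% trimmed mean between 125.009 and 125.015, so the arrays had been scaled to a common mean; array quantiles differ, so they had not been made equal. The software that summarised and scaled the probes is not given in the sources used here. All 22 columns match 1 sample each by the sample's own label.

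Of the probe sets, 37593 belong to soybean, 15820 to the oomycete Phytophthora sojae and 7530 to the soybean cyst nematode Heterodera glycines, as their identifiers state, and 227 others were left out of the tests. The 23350 oomycete and nematode probe sets set a floor per array, their 95th percentile, which lay between 11.8 and 22.1. A soybean probe set was tested when it exceeded the floor on at least 3 arrays, which 32776 did. The table of gene names gives 1 symbol to 8677 soybean probe sets, several to 370 and none to 28546, and no gene was named from a probe set with several. It names 6029 genes, of which 5701 remained after the filter and 1019 had an informative name; 21 gene identifiers were absent from the RefSeq table used to update symbols. No genome build is tied to the array in the sources used here, so no coordinates are given. A gene was represented by its probe set of highest mean over all arrays. Of 1640 genes with several probe sets, 3 in R20 against C20 and none in the other same-age comparisons had probe sets called in both directions. At both R20 and R30, 6 of the 7 VSPA probe sets and all 3 VSPB probe sets were called.

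Groups followed the sample labels: C0, C15, C20 and C30 (untreated), D15 (bud removal) and R20 and R30 (regrowth). The design text speaks of 3 replicate time courses without saying that a replicate number marks one of them, and does not say how many plants a sample pooled, so p-values measure the spread between these samples. The highest correlation between 2 arrays was 0.961, and none were alike enough to be 1 hybridisation deposited more than once. Replicate numbers did not pair the samples and were used as a block only as an alternative.

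Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with 1 coefficient per group over all 22 arrays, lmFit, contrasts.fit and eBayes with a variance trend. P-values were adjusted per comparison by the Benjamini-Hochberg method and a probe set was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of dim genes. Where the probe set of a gene was not above the floor on any array of a group, only a bound is given, as at least N-fold: the brighter group's mean log2 value against the mean over the dim group's arrays of the higher of the array's floor and the probe set's own signal. Another probe set of GASA14 was above the floor on 1 of 3 C20 arrays. Comparisons were D15 with C15, R20 with C20, R30 with C30, the changes of these differences from D15 to R20 and R30, and C30 with C0. Each probe set had 3 or 4 arrays per group.

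Before the data were examined 44 gene lists had been fixed by symbols and words of gene titles. The name table held symbols alone, so the members were chosen anew from it, and the set of lists changed with them. Of the 44 planned lists 27 were kept by name, with new members, and 17 were dropped or merged into others. Of the 47 used, 20 were added or formed by merging. Among them were those of bZIP and NAC genes, drought and cold regulators, ER chaperones, phosphate, fatty acids, tocopherol and carotenoids, and sieve elements. This departure from the plan was made after array summaries, correlations between arrays and control probe sets had been looked at, and before any comparison was fitted. The added or merged lists made up 8 of the 15 called in D15 against C15, 2 of 4 in R20, 4 of 10 in R30 and 7 of 13 in C30 against C0. In the interactions they were 2 of 3 and 4 of 9. Of the 47 lists, 42 had at least 5 measured genes and were tested with camera of limma, at a preset inter-gene correlation of 0.01 and on 1 probe set per gene. The Benjamini-Hochberg adjustment ran over these 42 lists, and the test was repeated with a correlation estimated per list. Counts of list members adjusted over the list alone use the same limma p-values adjusted within the list.

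The rule for named genes was fixed before the data were examined: the 8 largest rises and 8 largest falls per same-age comparison (4 and 4 for C30 against C0) among called genes with an informative name, up to 3 called members of each list described or else its member with the smallest p, and VSPA and VSPB throughout. Members named for the lists of C30 against C0 (SGR1, LHCP, XET1) and the list members given beside the interactions were chosen from the called members or by the D15 rule.

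The procedure was tested on simulated data with the real means and spreads, 32776 probe sets and 200 changed ones. For D15 against C15 it recovered 4%, 38%, 66% and 98% of changes of 1, 2, 3 and 6 on the log2 scale, with 110 calls of which 7 were false. For R20 against C20 it recovered 6%, 40%, 78% and 88%, for R30 against C30 6%, 34%, 68% and 98%, and for C30 against C0 6%, 40%, 72% and 98%. For the change of the difference from D15 to R20 it recovered 35.8%, 44.8% and 90.9% of changes of 2, 3 and 6. In a separate simulation of 5701 genes 5 lists were shifted by 1 log2 unit in D15. In D15 against C15 camera called 5 of the 5 and 0 of 37 others. Both simulations drew genes independently and with the same spread on every array. They left out correlation between genes and unequal array quality, so their false calls do not give those to expect here. Other splits of the real D15 and C15 arrays gave up to 10 called lists.

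Alternatives listed before the data were examined were no variance trend, no filter, a stricter filter, quantile normalization, median centring, array weights, the replicate number as a block, a pseudocount of 16, a 2-fold minimum, a fit on the compared groups alone, and leaving out each array in turn; for the lists, also an estimated correlation and the mean of all probe sets of a gene. An RNA integrity covariate, the omission of 3 arrays together and gene-by-gene array weights were added after the data had been seen. Among list calls and correlations, the earlier alternatives covered only the lists of D15 against C15 and the correlation of D15 with R20. For the others they were added later. The correlations of R20 with R30, of R20 with C30 against C0 and of R30 with C20 against C0 were not planned. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.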

Results

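Transcript signal was measured in mature leaves of soybean (Glycine max) on 22 Affymetrix Soybean GeneChips, arrays whose probe sets each report the signal of 1 transcript or a few closely related transcripts. In the treated plants all axillary and terminal buds were taken off daily for 15 days, starting at a plant age of 30 days, which removed the growing shoot tips that draw on the products of mature leaves. Buds were then left to regrow for 15 days. Leaves were sampled at the end of bud removal (D15, plant age 45 days, n = 3), after 5 days of regrowth (R20, age 50 days, n = 3) and after 15 days of regrowth (R30, age 60 days, n = 3). Untreated plants grown side by side gave the controls C15, C20 and C30 of the same ages (n = 3 each), and C0 (age 30 days, n = 4) was the start of the time course. The series addressed the effect of bud removal on gene expression in the leaf. Of 37593 soybean probe sets, 32776 rose above the signal floor on at least 3 arrays and were tested. The median soybean signal per array lay between 57.1 and 81.3 on 21 arrays and was 38.2 on R20 replicate 3, where 60.3% of the soybean probe sets lay above the floor. The actin 3' over 5' signal ratio, which rises when RNA is degraded, was 136 on that array and between 2.29 and 8.37 on the others. The ratio of the hybridisation controls BioC over BioB was 2.29 to 3.04 on the C20 and R20 arrays and 0.877 to 1.25 on all other arrays. Each same-age comparison thus lay within arrays of like ratio, and comparisons across ages that involved C20 or R20 did not. The C20 and R20 arrays still differed without overlap in the signal of another hybridisation control, cre, at 4646 to 5603 and 7259 to 15615. Their signal floors, 11.8 to 13.0 and 14.4 to 21.8, did not overlap either. Errors of log2 fold changes are standard errors from limma, errors of signals are standard deviations over the arrays of a group, and the number of arrays limits the precision.

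**Figure D1:**
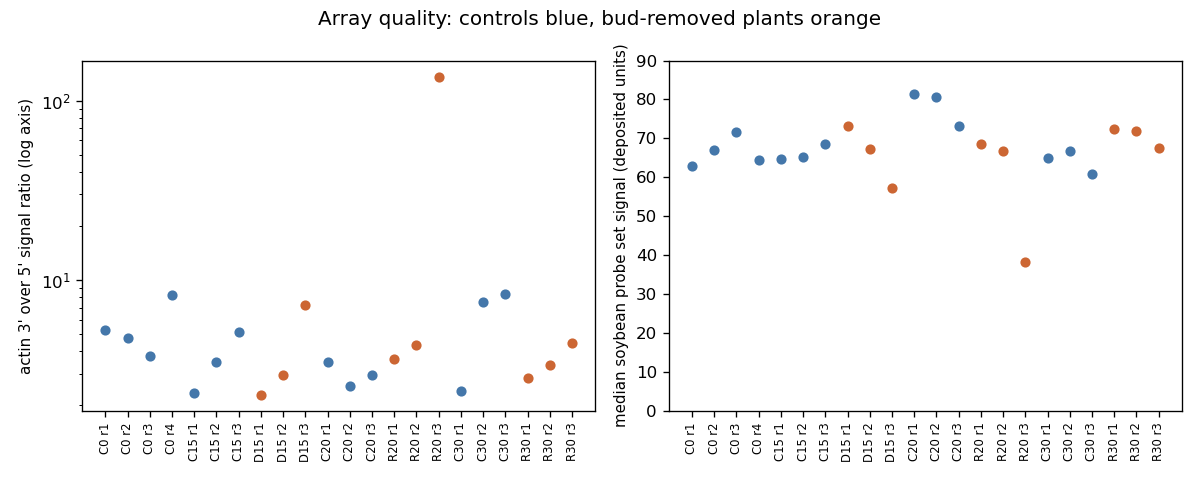
Actin 3' over 5' signal ratio (left, log axis) and median soybean probe set signal (right, deposited units) on each of the 22 arrays, with controls in blue and bud-removed plants in orange. R20 replicate 3 stands at a ratio of 136 and a median of 38.2, apart from the other 21 arrays.

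The first comparison set leaves after 15 days of bud removal against untreated leaves of the same age. The largest rise among called genes with an informative name was in AG1, whose signal was 3744 ± 349 in D15 and 307 ± 508 in C15 (log2 fold change 6.15 ± 1.25, adjusted p = 0.0478, higher in 3 of 3 arrays). CHI1B1, a chalcone isomerase of flavonoid synthesis, rose by 2.55 ± 0.52 on the log2 scale, the glutathione S-transferase gene GSTU59 by 2.41 ± 0.40 (adjusted p = 0.0175), the small heat shock protein gene HSP23.9 by 2.18 ± 0.43 and the lipoxygenase gene LOX1.4 by 1.93 ± 0.40. SGT3 (3.31 ± 0.64), GmCSyGT3 (2.58 ± 0.51), EN2 (2.55 ± 0.46) and NAC6, a NAC transcription factor gene (2.02 ± 0.42), also rose. VPE2, which encodes a vacuolar processing enzyme, a protease, fell by 3.33 ± 0.67, from a signal of 8012 ± 4063 in C15 to 842 ± 647 in D15. These were the 10 genes with an informative name among 74 changed probe sets, of which 48 were higher and 26 lower at an adjusted p under 0.05, while 3912 had an unadjusted p under 0.05. The calls of AG1, GmCSyGT3, HSP23.9, VPE2 and LOX1.4 ended under median centring, and those of HSP23.9, NAC6 and LOX1.4 under quantile normalization.

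The vegetative storage proteins, glycoproteins that accumulate in soybean leaves as a nitrogen reserve, had high signals in D15 but did not pass the test. VSPB stood at 11578 ± 1444 in D15 and 508 ± 818 in C15 (log2 fold change 6.63 ± 1.51, adjusted p = 0.0742), and VSPA at 9006 ± 1067 and 1239 ± 1994 (5.02 ± 1.35, adjusted p = 0.12). Both were higher in all 3 D15 arrays than in any C15 array, and C15 replicate 1, with a VSPA signal of 3542, lay far above the other C15 arrays at 134 and 42.9. Adjusted over the list alone, 2 of the 2 genes were higher. The probe sets of these related genes may detect both transcripts, which was not tested, so their split between VSPA and VSPB is uncertain.

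Of the 47 gene lists used, 20 were added or merged after the plan had been fixed. Of 42 lists tested with camera in D15 against C15, 15 were called, 9 shifted up and 6 down, and 1 of the 15 was also called with an estimated inter-gene correlation. Without C15 replicate 3 the count was 9, with 6 up and 3 down. The list also called with an estimated correlation was itself added or merged after the plan. It held drought and cold regulators, transcription factor genes such as those of the DREB type. None of its 10 measured genes passed the test over all probe sets, all 10 had lower fitted values in D15 (median log2 fold change -0.84), 3 were lower adjusted over the list alone, and the list's adjusted p was 0.000355, or 0.0281 with an estimated correlation. DREB1 stood at 420 ± 17.1 in D15 and 964 ± 269 in C15 (log2 fold change -1.16 ± 0.28, adjusted p = 0.091). The lipoxygenases, enzymes that oxidise polyunsaturated fatty acids, shifted up with 1 of 7 genes risen, 4 higher adjusted over the list alone and a median log2 fold change of 1.41 (adjusted p = 0.000648, and adjusted p = 0.385 with an estimated correlation). Of 16 genes of isoflavonoid and pterocarpan synthesis none passed and 1 was higher adjusted over the list alone (median 1.55, adjusted p = 0.00163, and adjusted p = 0.42 with an estimated correlation). The chalcone reductase gene CHR5 came closest at 2.88 ± 0.68 with an adjusted p of 0.0849. In the flavonoid core pathway 1 of 12 genes rose, CHI1B1, and 5 were higher adjusted over the list alone (adjusted p = 0.00557, and adjusted p = 0.145 with an estimated correlation).

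Of the heat shock proteins 1 of 6 rose in D15 against C15 and 2 were higher adjusted over the list alone (adjusted p = 0.00557, and adjusted p = 0.33 with an estimated correlation). Of 8 ER chaperones, which fold proteins in the endoplasmic reticulum, none passed over all probe sets and 5 were higher adjusted over the list alone (median 1.26, adjusted p = 0.00316, and adjusted p = 0.385 with an estimated correlation). PDIM-1, of the protein disulfide isomerase family, had 1.48 ± 0.34. None of 11 pathogenesis-related genes passed and 2 were higher adjusted over the list alone (adjusted p = 0.00918, and adjusted p = 0.517 with an estimated correlation). Among phosphate transport and acid phosphatase genes none of 8 passed, and 5 were higher and 1 lower adjusted over the list alone (adjusted p = 0.0352, and adjusted p = 0.385 with an estimated correlation). PAP25, a purple acid phosphatase gene, had 2.04 ± 0.59. Of 36 glutathione S-transferase genes 1 rose, GSTU59, with 2 adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.554 with an estimated correlation). None of 18 fatty acid genes passed, 1 was higher adjusted over the list alone, and FAD2-2, an oleate desaturase gene, had 1.60 ± 0.45 (adjusted p of the list 0.0484, and adjusted p = 0.545 with an estimated correlation).

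Of the lists shifted down in D15, senescence had 1 of 5 genes fallen, VPE2, and 3 lower adjusted over the list alone (median -2.06, adjusted p = 0.00409, and adjusted p = 0.385 with an estimated correlation). In tocopherol and carotenoid synthesis none of 14 passed and 1 was lower adjusted over the list alone, with HPT1, the homogentisate phytyltransferase gene of tocopherol synthesis, at -3.29 ± 0.78 and an adjusted p of 0.085 (adjusted p of the list 0.0212, and adjusted p = 0.435 with an estimated correlation). Of 20 NAC genes 1 rose, NAC6, against the direction of the list, and adjusted over the list alone 1 was higher and 3 were lower (median -0.81, adjusted p = 0.0355, and adjusted p = 0.565 with an estimated correlation). None of 56 bZIP genes passed and 1 was lower adjusted over the list alone. The gene bZIP84 had -2.64 ± 0.56 with an adjusted p of 0.0579 (adjusted p of the list 0.00919, and adjusted p = 0.515 with an estimated correlation). None of 11 genes of nitrate, ammonium, urea and ureide metabolism passed, either over all probe sets or over the list alone. NIR, nitrite reductase, had -1.80 ± 0.72 (adjusted p of the list 0.0484, and adjusted p = 0.435 with an estimated correlation).

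The count of 74 in D15 against C15 rested on single arrays: it was 1135 without C15 replicate 1, 1 without C15 replicate 2 or without D15 replicate 2, 7 without C15 replicate 3 or without D15 replicate 1, and 30 without D15 replicate 3. Without D15 replicate 3 the excess of higher calls turned, to 13 higher and 17 lower. The count was 0 when the 6 arrays of these groups alone were fitted with limma, 22 without the variance trend, 45 under median centring, 148 with a pseudocount of 16, and 3332 when C0 replicate 4, C15 replicate 1 and R20 replicate 3 were left out together, a setting chosen after seeing the data.

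**Figure D2:**
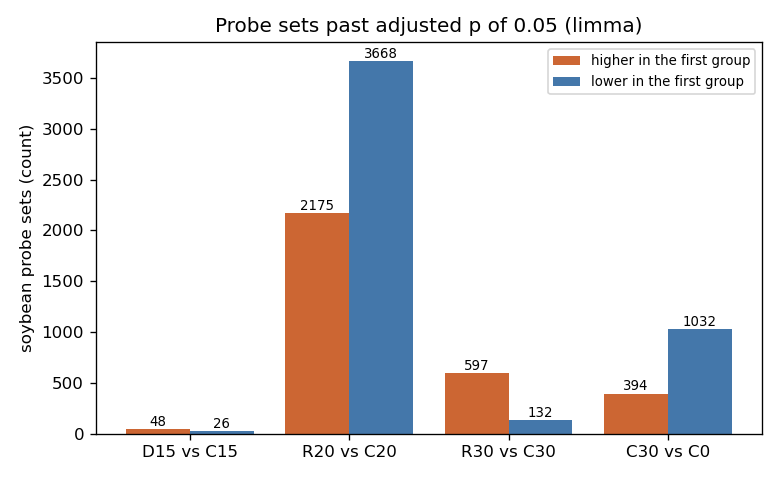
Number of soybean probe sets higher (orange) or lower (blue) in the first group of each comparison at an adjusted p under 0.05 in limma. The counts are 48 and 26 in D15 against C15, 2175 and 3668 in R20 against C20 (3805 and 1707 under median centring), 597 and 132 in R30 against C30, and 394 and 1032 in C30 against C0.

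The second comparison set leaves after 5 days of regrowth against untreated leaves of the same age. VSPB rose from a signal of 25.1 ± 5.99 in C20 to 11747 ± 1126 in R20 (log2 fold change 8.84 ± 1.51, adjusted p = 0.00153) and VSPA from 10.6 to 31.1 on the C20 arrays to 9151 ± 1918 in R20 (8.72 ± 1.35, adjusted p = 0.000777), both in 3 of 3 arrays. AG1 was not above the floor in C20 and at least 446-fold higher in R20. The gibberellin-regulated GASA9 rose by 7.34 ± 1.41 on the log2 scale, CYP76O2, a cytochrome P450 gene, by 6.43 ± 0.76, the Kunitz trypsin inhibitor gene KTI-2 by 5.97 ± 1.02 and the expansin gene EXP4 by 5.93 ± 1.91. The probe set of GASA14 was not above the floor in C20 and at least 24.9-fold higher in R20. MS and ICL1, malate synthase and isocitrate lyase of the glyoxylate cycle, fell by 7.06 ± 1.76 and 5.62 ± 1.25. BCH3, of the beta-carotene hydroxylases, fell by 5.86 ± 0.99. NAC3 fell by 4.53 ± 0.97, HPT1 fell by 4.18 ± 0.78 and BZIP61 fell by 3.80 ± 0.61. NAC17 and GSTU5 were not above the floor in R20 and at least 2.83-fold and 1.59-fold lower than in C20, though both calls ended under median centring. In all, 5843 probe sets changed, 2175 higher and 3668 lower, about a median log2 fold change of -0.27 over all probe sets tested. That median was -0.09 after quantile normalization, with 2281 higher and 2400 lower, and 0.20 after median centring, with 3805 higher and 1707 lower, so directions in R20 hold relative to these medians.

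All 7 lipoxygenase genes rose in R20 against C20, and all 7 adjusted over the list alone, with LOX10 at 5.66 ± 0.98, LOX7 at 4.78 ± 0.81 and VLXC at 3.18 ± 0.53 (adjusted p of the list 1.97e-05, and adjusted p = 0.682 with an estimated correlation). Under quantile normalization 5 of the 7 passed and under median centring 7. Of 36 glutathione S-transferase genes 10 rose and 2 fell, with 14 and 2 adjusted over the list alone. GSTU28 rose by 4.07 ± 0.66, GSTU59 by 3.98 ± 0.40 (adjusted p = 3.36e-05) and GSTU26 by 3.87 ± 1.13 (adjusted p of the list 0.0193, and adjusted p = 0.795 with an estimated correlation). Under median centring 17 of these genes rose and 1 fell, and under quantile normalization 8 rose and 2 fell. Of 56 bZIP genes 9 fell and none rose, with 8 fallen adjusted over the list alone. under median centring 5 of these genes fell and 1 rose, and under quantile normalization 6 fell. Besides BZIP61, BZIP36 fell by 2.91 ± 0.50 (adjusted p of the list 0.000445, and adjusted p = 0.733 with an estimated correlation). The median of the bZIP list was -0.50 as deposited and -0.03 under median centring. Of 20 NAC genes 6 fell and 1 rose, with 7 and 2 adjusted over the list alone. NAC12 fell by 3.31 ± 0.81 (adjusted p of the list 0.0231, and adjusted p = 0.795 with an estimated correlation). Under median centring 3 NAC genes fell and 2 rose, and under quantile normalization 4 fell and 1 rose. These 4 lists, 2 up and 2 down, were the ones called of 42 in R20, and 7 were called without C20 replicate 3. Without R20 replicate 3 the calls were 3 up and 1 down, and without C20 replicate 1 they were 2 up and 1 down.

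Members of lists that were not called also moved in R20. Of 9 genes of jasmonate synthesis and signalling 5 rose and 1 fell, with the same numbers adjusted over the list alone (adjusted p of the list 0.146). The allene oxide cyclase genes AOC6, AOC3 and AOC4 rose by 2.32 ± 0.59, 1.93 ± 0.37 and 1.76 ± 0.52. In the flavonoid core pathway 5 of 12 rose, 7 adjusted over the list alone, among them the chalcone synthase gene CHS8 (2.51 ± 0.75) and the chalcone isomerase gene CHI2-A (2.12 ± 0.63; adjusted p of the list 0.146). Under median centring 7 rose and under quantile normalization 4, without CHS8. Of 11 genes of nitrate, ammonium, urea and ureide metabolism 3 rose, also adjusted over the list alone: the nitrate reductases INR2 (3.45 ± 0.59) and INR1 (2.74 ± 0.50), and EU3 (1.31 ± 0.31; adjusted p of the list 0.288). Of 20 gibberellin genes 5 rose and 1 fell, with the same numbers adjusted over the list alone (adjusted p of the list 0.115), and under median centring 7 rose and none fell. Of the 10 drought and cold regulators 3 fell, DREB2 (-2.82 ± 0.67), DREB3 (-1.49 ± 0.31) and DREB1 (-1.02 ± 0.28), and 1 rose, with 4 and 2 adjusted over the list alone (adjusted p of the list 0.0978). Under median centring 2 of them fell and 2 rose, and the call of DREB1 ended. In tocopherol and carotenoid synthesis 3 of 14 fell, also adjusted over the list alone (adjusted p of the list 0.0563), and the list's median was -0.48 as deposited and -0.00 under median centring. Of 4 protease inhibitor genes, too few for the list test, 3 rose, also adjusted over the list alone: KTI-2, KTI-3 (4.93 ± 0.96) and the Bowman-Birk inhibitor gene BBI-1 (3.19 ± 1.06), whose call ended under quantile normalization. Of 48 WRKY genes 7 fell and 2 rose as deposited, and the same numbers adjusted over the list alone, but under median centring 2 fell and 6 rose, and under quantile normalization 2 fell and 1 rose (adjusted p of the list 0.118).

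These gene groups moved beside the signs of RNA quality on R20 replicate 3, with its actin ratio of 136. Without that array 3016 probe sets were called, 1445 higher and 1571 lower. Without C20 replicate 1 the count was 2603 and without C20 replicate 2 it was 1552, with 792 higher and 760 lower. With the 6 arrays of C20 and R20 alone in the fit 2072 were called, 1233 higher and 839 lower, so the excess of lower calls turned, and 43 of the 96 named genes called in R20 lost the call. With the actin ratio as a covariate, a fit chosen after the results had been seen, 29 of the 96 lost it.

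The third comparison set leaves after 15 days of regrowth against untreated leaves of the same age. VSPB rose from a signal of 24.8 ± 17.4 in C30 to 10584 ± 2339 in R30 (log2 fold change 9.03 ± 1.51, adjusted p = 0.00264) and VSPA from 27.1 ± 13.0 to 8609 ± 1112 (8.39 ± 1.35, adjusted p = 0.00182), in 3 of 3 arrays each. The trypsin inhibitor genes KTI-2 and KTI-3 rose by 7.15 ± 1.02 and 6.15 ± 0.96, LOX7 by 6.75 ± 0.81 (adjusted p = 0.000197), AG1 by 6.77 ± 1.25 and SALI5-4A by 6.12 ± 0.61 (adjusted p = 3.58e-05). GASA9 was not above the floor in C30 and at least 38.1-fold higher in R30. HPT1 fell by 4.38 ± 0.78, BCH3 by 3.94 ± 0.99, NAC3 by 3.82 ± 0.97, NAC27 by 3.51 ± 0.88, NAC4 by 3.34 ± 0.71, AOX1, of the alternative oxidases of mitochondria, by 2.94 ± 0.49 and PUR1 by 2.79 ± 0.66. GLYI-6 was not above the floor in R30 and at least 3.61-fold lower than in C30. In all, 729 probe sets changed, 597 higher and 132 lower.

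**Figure D3:**
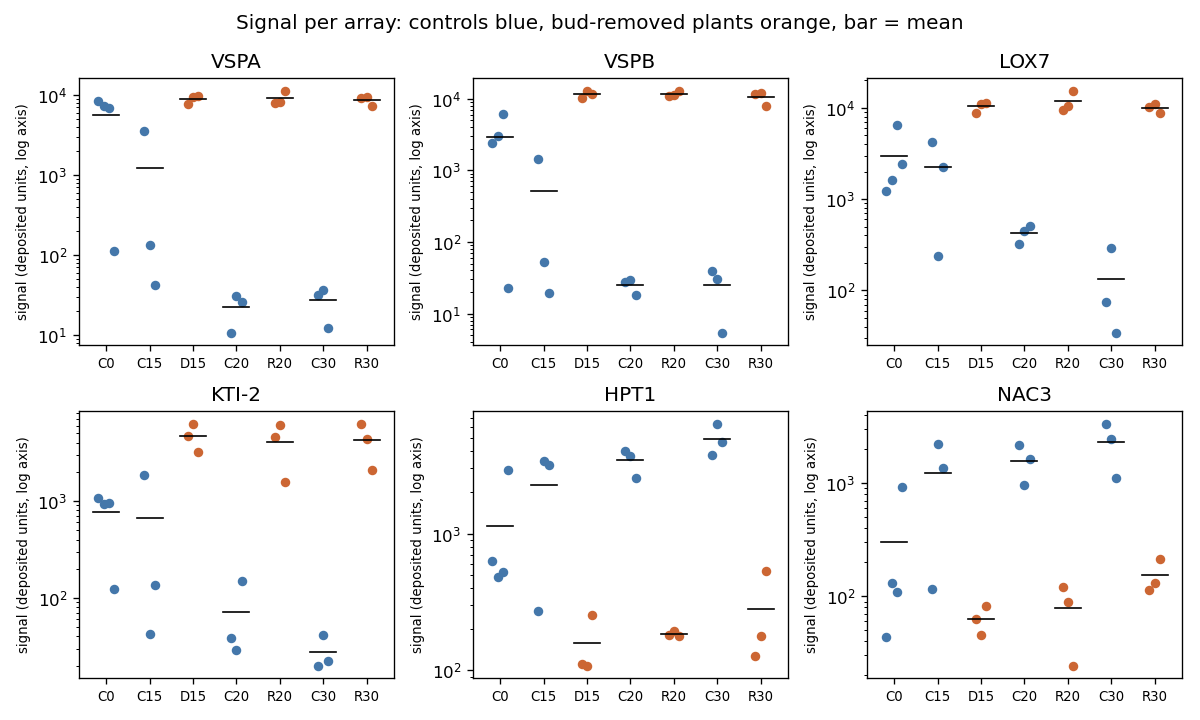
Signal of 6 named genes on each array (deposited units, log axis), with controls in blue, bud-removed plants in orange and a bar at each group's mean. VSPA has means of 9006, 9151 and 8609 in D15, R20 and R30, while C0 replicate 4 has a VSPA signal of 113 and C15 replicate 1 one of 3542.

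In R30 against C30 10 of 42 lists were called, and none of them with an estimated correlation. Of 7 lipoxygenase genes 5 rose, all 7 adjusted over the list alone, with LOX10 at 5.44 ± 0.98 and VLXC at 4.24 ± 0.53 (adjusted p of the list 3.31e-10, and adjusted p = 0.206 with an estimated correlation). Of 20 gibberellin genes 4 rose and 5 adjusted over the list alone, among them SLR1 (2.53 ± 0.64), of the DELLA repressors of gibberellin response, and GASA29 (2.42 ± 0.52; adjusted p of the list 0.00157, and adjusted p = 0.52 with an estimated correlation). Of 9 jasmonate genes 1 rose, AOC3 (1.52 ± 0.37), and 3 adjusted over the list alone (adjusted p of the list 0.0144, and adjusted p = 0.464 with an estimated correlation). The chalcone reductase gene CHR5 (2.85 ± 0.68) was the 1 of 16 isoflavonoid genes that rose, also adjusted over the list alone (adjusted p of the list 0.0275, and adjusted p = 0.636 with an estimated correlation). The calls of AOC3 and CHR5 ended under median centring, where 3 gibberellin genes rose, and under quantile normalization all 7 lipoxygenase genes rose. Among 11 pathogenesis-related genes SGlu11, a glucanase gene, rose (5.28 ± 1.14), also adjusted over the list alone (adjusted p of the list 0.0335, and adjusted p = 0.636 with an estimated correlation). Of 10 genes of expansins, xyloglucan transferases and proline-rich wall proteins 1 rose, the expansin gene CIM1, at least 9.08-fold higher, and 4 adjusted over the list alone (adjusted p of the list 0.0179, and adjusted p = 0.52 with an estimated correlation).

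Of the lists shifted down in R30, tocopherol and carotenoid synthesis had 2 of 14 genes fallen, HPT1 and BCH3, and 4 adjusted over the list alone (median -1.15, adjusted p = 0.000707, and adjusted p = 0.464 with an estimated correlation). Of 20 NAC genes 3 fell and 1 rose, with 5 and 2 adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.636 with an estimated correlation). None of 56 bZIP genes passed, either over all probe sets or over the list alone (median -0.32, adjusted p = 0.0145, and adjusted p = 0.636 with an estimated correlation). None of 5 senescence genes passed and 4 were lower adjusted over the list alone. SGR1, a stay-green gene of chlorophyll breakdown, had -2.54 ± 0.87 (adjusted p of the list 0.0292, and adjusted p = 0.636 with an estimated correlation). Outside the called lists, 2 of 36 glutathione S-transferase genes rose, GSTU28 (3.94 ± 0.66) and GSTU59 (3.13 ± 0.40), and GST24 fell (-2.39 ± 0.60), with 7 and 1 adjusted over the list alone (adjusted p of the list 0.0565). In the flavonoid core pathway 2 of 12 rose, CHI2-A (3.84 ± 0.63) and CHI1B1 (2.83 ± 0.52), and 3 adjusted over the list alone (adjusted p of the list 0.0777). INR2 (2.33 ± 0.59), INR1 (1.90 ± 0.50) and EU3 (1.50 ± 0.31) rose again, the 3 of 11 in their list, also adjusted over the list alone (adjusted p of the list 0.233). All 3 calls ended under median centring, where the list's median was -0.01 instead of 0.13. Single arrays moved the count of 729, which was 190 without R30 replicate 1, 231 without R30 replicate 2, 357 without C30 replicate 3, 422 without C30 replicate 2 and 1132 without C30 replicate 1.

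**Figure D4:**
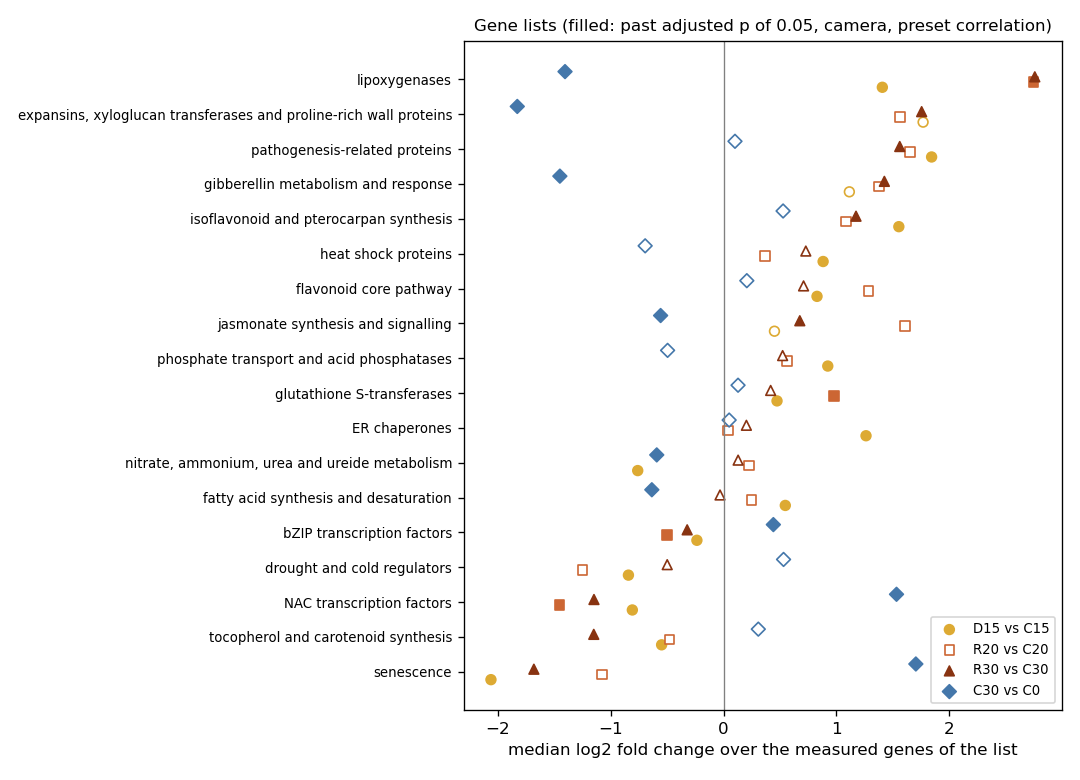
Median log2 fold change over the measured genes of each list called in at least 1 same-age comparison, for the 3 same-age comparisons and for C30 against C0. Filled markers passed an adjusted p of 0.05 in camera with the preset correlation. The lipoxygenases lie at 1.41, 2.75 and 2.76 in D15, R20 and R30. In R20 the bZIP and the tocopherol and carotenoid medians of -0.50 and -0.48 move to -0.03 and -0.00 under median centring.

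Whether the difference from the control changed between the end of bud removal and regrowth was tested as an interaction. No probe set passed for R20 against D15, where limma gave 3690 at an unadjusted p under 0.05, and none for R30 against D15, with 733. For VSPB the fitted log2 difference from the control was larger by 2.21 ± 2.14 in R20 than in D15 (adjusted p = 0.704) and for VSPA by 3.69 ± 1.90 (adjusted p = 0.465), so the storage protein genes that passed the test in R20 and R30 were not shown to respond differently from D15. For LHCP, a light-harvesting chlorophyll protein gene, the fitted difference was larger by 2.72 ± 0.79 in R20 than in D15 (adjusted p = 0.328). The first count was 13 without D15 replicate 3 and 2 without R20 replicate 3. Of 42 lists 3 were called in the first interaction and 9 in the second, none with an estimated correlation, and the arrays of R20 and C20 differ from those of D15 and C15 in the ratio of the hybridisation controls.

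Across the 32776 probe sets, which are not independent replicates, the log2 fold changes of D15 and R20 against their own controls correlated with Pearson's r = 0.54 (Spearman's rho = 0.45), those of D15 and R30 with 0.66 (0.60) and those of R20 and R30 with 0.51 (0.39). These comparisons share no array. Of the 74 probe sets changed in D15, 50 also changed in R20, 39 higher and 11 lower in both, where independent lists would share 3.19 and 2.91. With R30 they shared 49, 38 higher and 11 lower in both, where independent lists would share 0.874 and 0.105. R20 and R30 shared 420 higher and 84 lower, where independent lists would share 39.6 and 14.8.

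The change in untreated leaves over the same 30 days served as the background, in C30 against C0. VSPA fell by 6.69 ± 1.26 on the log2 scale, from a signal of 5696 ± 3780 in C0 to 27.1 ± 13.0 in C30 (adjusted p = 0.00624), and VSPB by 5.67 ± 1.41, with ranges of the groups that overlapped. CYP76O2 fell by 6.54 ± 0.71 (adjusted p = 0.000277), and GASA9 and GASA11 were not above the floor in C30 and at least 88.1-fold and 16.5-fold lower than in C0. ICL1 rose by 5.13 ± 1.17, BBI-1 by 4.78 ± 0.99, MYB68, a MYB transcription factor gene, by 4.02 ± 0.81 and NAC3 by 3.74 ± 0.91. In all, 1426 probe sets changed, 394 higher and 1032 lower.

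In C30 against C0 13 of 42 lists were called, 4 up and 9 down, and all 13 calls were lost with an estimated correlation. Without C30 replicate 1 the count was 8, with 3 up and 5 down. Of the 48 WRKY genes 8 rose and none fell, with 16 and 1 adjusted over the list alone, and of the 20 NAC genes 6 rose and 2 fell, with 10 and 2 adjusted over the list alone (adjusted p = 0.000336 and 0.000345, and adjusted p = 0.437 and 0.389 with an estimated correlation). Of 5 senescence genes 1 rose, SGR1, and 4 adjusted over the list alone, and of 56 bZIP genes 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00567 and 0.00351, and adjusted p = 0.389 and 0.437 with an estimated correlation). Lipoxygenases had 3 of 7 fallen and 7 adjusted over the list alone, gibberellin genes 5 of 20 fallen and 1 risen with 10 and 2 adjusted over the list alone, and aquaporins, water channels of membranes, 5 of 22 fallen and 12 adjusted over the list alone (adjusted p = 5.95e-05, 0.000684 and 0.000336, and for each an adjusted p = 0.389 with an estimated correlation). The nitrate and ureide list had 4 of 11 fallen, with 4 fallen and 1 risen adjusted over the list alone, the jasmonate list 2 of 9, with 4 adjusted over the list alone, and the sieve element genes 3 of 6, with 4 adjusted over the list alone (adjusted p = 0.0251, 0.0223 and 0.00833, and for each an adjusted p = 0.389 with an estimated correlation). In photosynthesis 1 of 10 fell, LHCP, and 6 adjusted over the list alone, in the wall protein list 1 of 10 fell, XET1, a xyloglucan endotransglycosylase gene, and 6 adjusted over the list alone, and in fatty acid synthesis 2 of 18 fell and 5 adjusted over the list alone (adjusted p = 0.00915, 0.00982 and 0.044, and adjusted p = 0.483, 0.389 and 0.483 with an estimated correlation). Under median centring 6 WRKY genes rose and no gibberellin gene did, while 3 aquaporin, 2 lipoxygenase, 3 nitrate and ureide, 1 fatty acid and no wall protein genes fell. Under quantile normalization 3 aquaporin, 4 lipoxygenase, 4 gibberellin, 1 jasmonate and 2 sieve element genes fell. The other counts of these 13 lists stayed the same.

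The changes in untreated leaves and the differences between bud-removed and control leaves ran mostly in opposite directions. Across probe sets the log2 fold changes of D15 against C15 and of C30 against C0, which share no array, correlated with r = -0.48 (rho = -0.42), and of the 1426 probe sets changed in C30 against C0, 1229, or 86.2%, had the opposite sign in D15 against C15. For R20 against C20 the correlation was also -0.48 (rho = -0.38), and 616 of the 622 probe sets called in both comparisons had opposite signs. BBI-1 was among the exceptions, higher in both. For R30 against C30 the correlation was -0.41 (rho = -0.31) with C20 against C0, and 211 of 212 shared calls were opposite, where C20 against C0 called 2051 probe sets. The C20 and C0 arrays differ in the ratio of the hybridisation controls. The count of 1426 was 351 without C0 replicate 1, 383 without C0 replicate 2, 3023 without C0 replicate 4, 871 without C30 replicate 1 and 678 without C30 replicate 2. It was 72 when the 7 arrays of these groups alone were fitted.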

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

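The tests of explanations, the counts of other splits and the omission of 3 arrays together in this part were chosen only after the results had been seen.

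In C0, 4 of the 18 measures tested for a sample far from the others passed the critical value of Dixon's ratio for 4 samples. Chance gives about 1 in 20 groups for a single measure, but these measures are not independent. The floor and the percentage above it go together, as do VSPA and VSPB. The genes among the measures were those named for C30 against C0, most of them picked by calls that use these C0 arrays. C0 replicate 4 was far below the other C0 arrays in the log2 signal of VSPA, with a gap of 0.952 of the range, and of VSPB, with 0.831. C0 replicate 3 was apart in the signal floor, with 0.845, and in the percentage of soybean probe sets above it, with 0.845.

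C0 replicate 4 and C15 replicate 1 each correlated best with another group: replicate 4 of C0 at 0.876 with C15 against 0.841 with its own, and replicate 1 of C15 at 0.915 with D15 against 0.831. They were not alone, since C0 replicate 3, the other C15 arrays and all R20 and C30 arrays also correlated best with another group, and for C15 replicate 3 (0.910 against 0.846) and C30 replicate 1 (0.868 against 0.814) by a wider gap than for C0 replicate 4. RNA integrity stays open, because its test could not decide: with the actin slope removed, 0 of the 2 arrays moved to its own group. That slope rests mostly on R20 replicate 3, with an actin ratio of 136. C0 replicate 4 had the highest ratio of the C0 arrays, 8.27, and C15 replicate 1 the lowest of the C15 arrays, 2.34. An exchange of the labels of these arrays stays open: among 13 arrangements, the 12 exchanges of a C0 with a C15 array and none, it ranked 1, with a mean correlation within groups of 0.901 against 0.867 as labelled, and it may explain the VSPA signals of 113 and 3542, though it was found from the same arrays. No biological explanation was tested, and plants that differed in growth stage stay open.

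R20 against C20 called the most probe sets of the same-age comparisons, with more of them lower than higher, which turned to 1233 higher and 839 lower with these arrays alone in the fit. The degraded RNA of R20 replicate 3 was argued against as the whole cause of the count, since 3016 were called without that array, but stays open for the excess, which then was 1445 higher and 1571 lower. A hybridisation batch that separates R20 from C20 stays open, because its tests part: the spike ratio lay within the C20 range on 2 of the R20 arrays, but the cre signal was 4646 to 5603 on the C20 and 7259 to 15615 on the R20 arrays, without overlap, as was the signal floor. Array scaling stays open for the excess of lower calls, because median centring moves all probe sets of an array alike and decides nothing about it, with 69.0% of the calls higher, and under quantile normalization 48.7% were. The treatment as a whole, which the design names, stays open for the count. No group had its buds still removed at the age of R20, so R20 against C20 cannot separate regrowth from the bud removal before it.

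The differences between bud-removed and control leaves ran mostly opposite to the change of untreated leaves from C0 to C30. Among the explanations, leaves of bud-removed plants having stayed closer to C0 stays open, because 1 age rests on 2 arrays in doubt: fewer probe sets separated treated leaves than controls from C0 at 2 of 3 ages, with 1091 against 2051 for the R20 and C20 pair, 369 against 1426 for R30 and C30, and 316 for D15 against 0 for C15 (5005 and 3124 at an unadjusted p under 0.05), but without C0 replicate 4 and C15 replicate 1 these counts were 2363 against 4927, 989 against 3762, and 414 against 1769. The correlation between D15 against C15 and C30 against C0 was -0.476 as fitted, with a jackknife standard error of 0.197. Of the 3 arrays in doubt, C0 replicate 4 and C15 replicate 1 were argued against by a correlation of -0.595 without the 3. R20 replicate 3 is in neither of these comparisons, so its omission could not move this value. With the actin ratio as a covariate the correlation was -0.478. That fit cannot decide about RNA integrity, which stays open. Its slope rests mostly on R20 replicate 3, with an actin ratio of 136, which is in neither of these comparisons. A slower change of leaves with age under bud removal may hold, with the counts at both ages of regrowth on its side, and is a hypothesis found and examined on the same data. The counts of R20 and C20 against C0 compare arrays that differ in the ratio of the hybridisation controls. R20 and C20 also differ from each other in the cre signal and the signal floor.

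Lists called beyond what the calls of genes would show were also noted. In the test of whether the difference from the control changed between D15 and regrowth, 3 lists passed for R20: lipoxygenases up (adjusted p = 0.0129, camera), nitrate and ureide metabolism up (0.0079) and ER chaperones down (0.0079), with none of their 7, 11 and 8 genes called. For R30, 9 passed: lipoxygenases (5.95e-08), nitrate and ureide metabolism (9.17e-06), jasmonate (0.0288), gibberellin (0.0298), proteases (0.0298) and drought and cold regulators (0.0298) up, and ER chaperones (0.00218), heat shock proteins (0.0298) and fatty acid genes (0.0288) down. The nitrate and ureide, ER chaperone, drought and cold, and fatty acid lists were among those added or merged after the plan. With an estimated correlation the smallest adjusted p of these lists was 0.857 for R20 and 0.12 for R30. Among the 23350 oomycete and nematode probe sets, which the comparisons do not use, 1 was higher and 2 were lower in R20 than in C20, 2 were higher and 1 was lower in C30 than in C0, 1 was higher in the interaction of R20 with D15, and none was called in the other 3 comparisons. At an unadjusted p under 0.05 in limma, 1687 of them differed in R20 against C20. That number was 1229 in D15 against C15, 1282 in R30 against C30 and 1103 in C30 against C0. It was 1511 and 1159 in the interactions of R20 and R30 with D15.

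Other splits of the same arrays bear on each count. The 6 arrays of a same-age comparison allow 10 splits, too few for a share under 0.05, and 1 of 10 gave as many calls in D15 against C15 (74, highest other 1), in R20 against C20 (5843, highest other 0) and in R30 against C30 (729, highest other 20). For the lists 1 of 10 did so in D15 (15, highest other 10), 3 of 10 in R20 (4, highest other 6) and 1 of 10 in R30 (10, highest other 8). For C30 against C0, 3 of 35 splits gave as many calls (1426, highest other 3649), and 3 of 35 as many lists (13, highest other 14), so chance cannot be excluded; the split with 3649 set C0 replicate 4 with C30 replicates 2 and 3, and that with 3107 set C0 replicates 1, 2 and 3 against all others, which points to a structure of these samples around C0 replicate 4. For the interactions no count can be under the real 0, so 100 of 100 drawn splits had to give as many calls and decide nothing about it. The drawn splits regrouped the arrays of each age on their own, so a split could keep the real groups at 1 age. Their highest counts, 6260 for R20 and 3260 for R30, may thus hold a real difference and cannot show a structure of the samples. For the lists of the interactions 66 and 24 of 100 splits gave as many (real 3 and 9, highest other 14 and 15). Chance cannot be excluded, and for the same reason these shares do not measure it.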

How the results depend on the processing

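The actin covariate, the omission of C0 replicate 4, C15 replicate 1 and R20 replicate 3 together, and gene-by-gene array weights were chosen only after the results had been seen; the last because the default weights did not converge and their counts had been looked at. Before the data were examined, alternatives had been listed for the list calls of D15 against C15 but not for those of other comparisons. Among correlations this held for that of the D15 and R20 effects alone. Counts are given in the order D15 against C15, R20 against C20, R30 against C30, and C30 against C0, with 74, 5843, 729 and 1426 as reported. No fitted change of a named gene, direction of a called list in camera or correlation changed its sign. Part of this was fixed in advance. Fitted changes stay the same without the variance trend, under either change of filter and with only the compared arrays. Pearson correlations stay the same under median centring, and an estimated inter-gene correlation keeps the direction of a list. The larger of the higher and lower counts did change. In R20 against C20, with 2175 higher and 3668 lower as reported, it turned under median centring (3805 and 1707), with only the compared arrays (1233 and 839) and without C20 replicate 2 (792 and 760). In C30 against C0, with 394 and 1032, it turned under default (8886 and 7005) and gene-by-gene array weights (7870 and 6221). In D15 against C15, with 48 and 26, it turned without D15 replicate 3 (13 and 17) and under default weights (4767 and 4804). The first count moved to 22 without the variance trend, 45 under median centring and 148 with a pseudocount of 16, and stayed within 1.5 times under no filter, a stricter filter, quantile normalization and a 2-fold minimum; the other 3 counts stayed within 1.5 times under all of these. With only the compared arrays fitted, the first, second and last counts were 0, 2072 and 72. Default array weights gave 9571, 18721, 16372 and 15891, and 6453 and 1290 for the interactions of R20 and R30 with D15, which were 0 and 0 as reported; gene-by-gene weights gave 4333, 17371, 13471 and 14091, and 2663 and 8. The other splits of the C15 and D15 arrays gave up to 8349 and 6329 calls under these weights, so such counts do not need the real grouping. The actin covariate moved the first and last counts to 243 and 2219, and the omission of the 3 arrays gave 3332, 1944 (R30) and 5093 (C30 against C0). The interaction of R20 with D15 was 2 under median centring and 1 without the 3 arrays. With the replicate block, which is no pairing here, the first and last counts were 328 and 3520. Replicate 4 exists in C0 alone, so this fit also takes C0 replicate 4 out of every comparison, and its omission alone gave 3023 for the last count, so the part due to the block was not separated; same-numbered arrays correlated between -0.158 and 0.272 in their deviations in the same-age comparisons, and not every array matched its own number best. With each array left out in turn the first count ran from 1 (without C15 replicate 2 or D15 replicate 2) to 1135 (without C15 replicate 1), with 7 without C15 replicate 3 or D15 replicate 1 and 30 without D15 replicate 3. The second ran from 1552 (without C20 replicate 2) to 6355 (without R20 replicate 1), with 2603 without C20 replicate 1 and 3016 without R20 replicate 3. The third ran from 190 (without R30 replicate 1) to 1132 (without C30 replicate 1), with 231 without R30 replicate 2 and 357 and 422 without C30 replicates 3 and 2. The last ran from 351 (without C0 replicate 1) to 3023 (without C0 replicate 4), with 383 without C0 replicate 2 and 871 and 678 without C30 replicates 1 and 2. The interactions ran from 0 to 13 (without D15 replicate 3; 2 without R20 replicate 3) and from 0 to 0. The lists called ran from 9 (without C15 replicate 3) to 17 in D15 against C15, from 3 to 7 (without C20 replicate 3) in R20, from 7 to 12 in R30 and from 8 (without C30 replicate 1) to 13 in C30 against C0. The correlation of the D15 and R20 effects ran from 0.413 to 0.608, that of D15 and R30 from 0.570 to 0.684, that of R20 and R30 from 0.409 to 0.625, and those with the untreated change from -0.530 to -0.319 (D15), -0.571 to -0.398 (R20) and -0.459 to -0.298 (R30, with C20 against C0). The lists called, 15, 4, 10 and 13 as reported, were 1, 0, 0 and 0 with an estimated correlation, so almost all list calls rest on the preset correlation. With only the compared arrays fitted, 10 of the 10 named genes called in D15 lost the call, 43 of 96 in R20, 14 of 41 in R30 and 7 of 9 in C30 against C0. Without the variance trend 9, 10, 10 and 0 of them lost it, and under median centring 5, 12, 6 and 0. Under quantile normalization 3, 16, 0 and 0 lost it. Without the filter 4, 5 and 1 lost it in D15, R20 and R30. With 1 array of the comparison left out, counted per gene and array, calls in D15 were lost 48 times and kept 12 times. These numbers were 191 and 385 in R20, 96 and 150 in R30, and 14 and 49 in C30 against C0. In R20 29 named genes lost the call with the actin covariate and 27 without the 3 arrays, where the other comparisons lost none. Named genes not called as reported also gained a call without the 3 arrays, 24 in D15, 1 in R20 and 13 in R30. Apart from the weights, the causes were not tested, beyond the fewer arrays in the fits that leave arrays out. Signal over the floor limits dim genes, since 32776 of 37593 probe sets passed the filter and 60.3% lay above the floor on R20 replicate 3.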

Other observations

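The lists singled out in this part were chosen only after their results had been seen, and those of sieve elements, starch, phosphate, fatty acids and photosynthesis were added or merged after the plan.

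SEOS, of the sieve element occlusion family whose proteins form bodies in phloem, rose from a signal of 1213 ± 618 in C20 to 13155 ± 4605 in R20 (log2 fold change 3.51 ± 0.68, adjusted p = 0.00336, limma, 3 of 3 arrays) and from 415 ± 195 to 9999 ± 376 in R30 (4.71 ± 0.68, adjusted p = 0.000722); it stood at 10673 ± 3519 in D15 and 2434 ± 2371 in C15 (2.64 ± 0.68, adjusted p = 0.106). Of 6 measured sieve element genes none passed in D15, 3 rose in R20, or 2 under quantile normalization, and 1 rose in R30, also adjusted over the list alone apart from 1 lower in R20, and the list did not pass in either (adjusted p = 0.277 and 0.13, camera). Of 2 beta-amylase genes of starch breakdown named BMY1, 1 rose in R20 (3.13 ± 0.99) and R30 (4.83 ± 0.99), the only gene risen of 5 in the starch list, and the other did not pass in either. PAP25 rose in R20 (2.65 ± 0.59) and R30 (3.44 ± 0.59), and FAD2-2 in R20 (2.43 ± 0.45) and R30 (1.76 ± 0.45), where its call ended under median centring. Of 10 photosynthesis genes 3 rose in R20 and none in R30: LHCP (3.67 ± 0.56), CAB3, a chlorophyll-binding antenna gene (1.69 ± 0.32), and PSAD, of photosystem I (0.93 ± 0.23); under quantile normalization 2 rose and 1 fell. Of 22 aquaporin genes 4 rose and 1 fell in R20, led by SIP1-6 (4.20 ± 1.44), while 10 rose and none fell under median centring, and none passed in R30.

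Genes of nitrogen assimilation went both ways in R20. Of 15 genes of asparagine, glutamine, glutamate and alanine metabolism 4 rose and 2 fell, among them GS1-GAMMA (2.77 ± 0.62) and GS1alpha (-2.42 ± 0.49), both of cytosolic glutamine synthetase, and 5 and 3 adjusted over the list alone (adjusted p of the list 0.931, camera). Under median centring 5 rose and 1 fell, and under quantile normalization 2 rose and 1 fell. Of the 9 list genes used as references in expression work, such as actin, tubulin and GAPDH, 2 rose in R20, GAPDH (0.86 ± 0.29) and GAPC1 (0.75 ± 0.23), and the list's median was 0.45 as deposited and -0.02 under quantile normalization, where both calls ended and other genes of the list gave 1 risen and 1 fallen. Under median centring 4 rose. None of 7 genes of the circadian clock, a list fixed to show a difference in harvest hour, passed in D15, R20 or R30 (adjusted p of the list 0.0816, 0.942 and 0.46, camera). All 7 had lower fitted values in D15 than in C15. In C30 against C0 none passed and the list was not called, but its median log2 fold change was -1.31. The medians in D15, R20 and R30 were -0.87, 0.35 and -0.33. Of 7 nodule and root markers 2 rose in R20 and 1 in R30, N-36A in both (2.38 ± 0.65 and 3.00 ± 0.65). None of 3 seed markers and none of 3 markers of dividing cells passed in D15, R20 or R30. In C30 against C0 1 of the 3 seed markers rose, 1 of the 7 nodule and root markers fell and no marker of dividing cells passed. AG1, placed in the list of flowering and meristem genes by its symbol alone, was the only 1 of 7 that rose in D15 and in R30, and in R20 it was 1 of the 3 risen, with FT1A, of the florigen family (at least 4.63-fold higher), and AGL3L (1.41 ± 0.28). The call of AG1 in D15 ended under median centring.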
